A study of Botryllus schlosseri with 78 samples.

How the data were processed

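The labels describe 78 RNA sequencing libraries of Botryllus schlosseri: blood, cells sorted by integrin alpha-6 (IA6), aldehyde dehydrogenase (ALDH) or BSA, ampullae, whole bodies, and male colonies at 7 stages. Per the labels, libraries were made from poly-A RNA and sequenced as paired ends; 2 RNA kits and 2 sequencing centres are named, but no library is assigned to either, so no batch could enter the tests. Per the submitters' processing notes, Trim Galore, kallisto and RSEM were used, and no versions are given. The deposited signal values, made by the authors, are read here as TMM-scaled TPM, that is, TPM divided by a TMM scaling factor per library. The name of the table states TMM but not TPM, so the unit is inferred. Each library with values has 1 column. The table has 137 rows, here called transcripts, and 158 columns of values. Of these, 77 match a library of the labels, and 81 are not used here because no label describes them. The BSA library SB01-03 has no column and was not analysed. Library sums over the 137 rows lie between 308919 and 1466577, with a geometric mean of 957745. The TPM denominator is therefore close to this set of sequences, and the values are shares of the set, so that a rise in some transcripts lowers the others. TPM keeps no read totals, so depth per library is unknown. The lowest value of at least 1 in a library, a rough guide to depth, lay between 4.91 and 58.5 in whole bodies, 28.1 and 86.9 in ampullae, and 84.1 and 2337 in BSA libraries.

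Of the 10549 values used, 4559 are 0 and 24 lie between 0 and 1. Libraries with identical values were looked for and none was found (highest correlation of log2 values 0.995). The SMGO ampullae libraries named technical correlate at 0.874, within the range of 0.838 to 0.892 of the other SMGO pairs. They were averaged as 1 replicate, so SMGO ampullae count as 3: on the log scale for limma, and on the scale of the values for printed means, family totals and receptor sets. In means per colony over all its libraries, each library counts alike. The labels do not say whether other replicates are separate pieces, colonies or RNA preparations, so the p-values measure the spread between these libraries, which may be technical.

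Values were analysed as log2(value + 1), with a pseudocount of 1, and log2 differences are on that scale. A transcript was tested where its value was at least 1 in as many libraries (or colony means) as the smallest group holds. Differences of transcripts were tested with limma 3.58.1 in R 4.3.3, with a trend of the variance on the mean and Benjamini-Hochberg adjustment, at a threshold of 0.05. Comparisons were whole-body genotypes (F test), ampullae genotypes (F test), ampullae against whole bodies of SMGO and SMH (colony as block), stages of male colonies (F test, genotype as block), male genotypes (F test, stage as block), ALDH fractions (individual as block), IA6 fractions of 81A and 81C (individual as block), winners against losers (1 mean per ALDH individual), and 7 sample classes (F test on 1 mean per class and colony, 28 in all, with SMGO and SMH in both ampullae and whole bodies). The blocks are given by the labels. Adjustment was over all transcripts tested in a comparison and, for the FF, FcoR and remaining transcripts as lists fixed before the data were examined, over each list alone. Lists of markers for vasculature, germline, muscle and haemocytes were also fixed, but matched no transcript and gave no result.

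Family totals, the sums of FF or of FcoR values, were compared on the log2 scale with permutation tests: exact two-sided tests for pairs of groups, within colony or individual where both fractions or tissues were given, and 100000 resamples for tests over classes or stages. The overlap of receptor sets, the Jaccard index of transcripts at a value of at least 1, was tested by permuting colony labels, one-sided for a greater overlap within colonies; the side was not fixed beforehand. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9.

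Genes are named by a rule set before the data were examined: in each comparison the 10 transcripts past the threshold with the largest difference (10 per direction between 2 groups), the 5 FF and 5 FcoR transcripts with the highest mean, and, where fewer than 5 passed, the 5 with the smallest p. Names outside it are marked as picked later. The tests were run on simulated data made from the same libraries, with 30 transcripts changed in each of 20 simulations. At a log2 change of 2, limma recovered 64% of the changed transcripts for whole-body genotypes, 45.5% for ampullae genotypes, 69% for ampullae against whole bodies, 60.5% for stages, 69.5% for male genotypes, 40.5% for ALDH, 53% for IA6, 15.5% for winners and losers, and 2.5% for classes. At a change of 8 the shares were 95%, 81%, 98%, 88%, 99%, 80.5%, 86.5%, 40.5% and 38.5%. Of unchanged transcripts, 0.14% to 2.03% were called. The simulated values held no colony or individual effects and no switches between 0 and high values. The shares therefore describe the tests on such values and may differ for the real ones.

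Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter or a filter at 5, scaling to the receptor total, limma without trend or with robust variance, FcoR71 rows summed, blocks added or removed, technical libraries kept apart, all colonies in the tissue comparison, merged stages, other detection values, a mean of log2 values for family totals, correlation in place of the Jaccard index, and leaving out each replicate in turn. Added afterwards were a pseudocount of 500, scaling to the signalling genes, family totals as a ratio to the other transcripts, a detection value of 200, single colonies or lines, blood left out, SMGO and SMH in 1 class only, FcoR totals without FcoR72, and leaving out libraries that stood apart. The FcoR71 rows were the only ones whose names mark versions of a gene. Other splits of the samples, at most 100 per comparison, were counted for each limma comparison with at least 3 samples per group.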

Results

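Botryllus schlosseri is a colonial tunicate. Neighbouring colonies touch with their ampullae, the blind ends of the vessels in their shared tunic, and either fuse or reject each other according to the Fuhc locus. RNA sequencing covered 77 libraries with values, and each value is read as the TMM-scaled TPM of 1 transcript in 1 library. The table holds 137 transcripts: 45 with names in FF, read here as the fester family of allorecognition receptors, 69 with names in FcoR, 19 signalling proteins, and 4 products of the Fuhc locus. These 4 are BHF, FuHc-Sec, FuHc-Tm and HSP40L. No transcript carries the name fester or uncle fester. The FcoR sequences were found, per the series record, by searches that began from fester sequences. No chromosome positions are given, because the gene symbols of the reference annotation match none of the transcript names.

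The libraries comprised 3 of whole blood, each from 1 individual, 8 of cells sorted as positive for integrin alpha-6 (IA6) from 4 individuals, and 4 of IA6-negative cells from 2 of these. Cells sorted by aldehyde dehydrogenase (ALDH) gave a positive and a negative library for each of 4 individuals. Ampullae gave 16 libraries: 3 each of the lines SB825-FX, SB825-FEA and SB825-FDA, 4 of SMGO and 3 of SMH. Whole bodies of SB825, SKI, SMGO and SMH gave 3 libraries each. Male colonies of the genotypes M001, MADM and MDR gave 21 libraries, 1 for each of 7 stages of the weekly budding cycle. Vascular cells sorted with the reagent that the labels call BSA gave 5 libraries. Read totals were not given in the sources used here, so the depth of each library is unknown, and no floor for a value of 0 can be computed. The values of a library summed to between 308919 and 1466577, so each value is close to a share of these 137 transcripts. Means are given with their SD.

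The first question was how many receptors a colony carried. In whole bodies, 16.2 ± 1.93 FF transcripts (n = 4 colonies) and 44.6 ± 4.58 FcoR transcripts had a value of at least 1. In male colonies the numbers were 18.6 ± 1.87 and 41.2 ± 2.84 (n = 3 genotypes), and in ampullae 17.3 ± 1.55 and 35.8 ± 1.58 (n = 5 lines or colonies). ALDH-positive cells held 19.2 ± 1.71 FF and 42.8 ± 3.86 FcoR transcripts (n = 4 individuals), IA6-positive cells 15.0 ± 2.27 and 37.4 ± 1.44 (n = 4). Blood held 16 FF transcripts in each of the 3 individuals and 36.7 ± 1.53 FcoR transcripts. The BSA libraries ranged from 0 to 19 FF transcripts, and 2 of them, SB07-09 and SB10-11, held 0 and 2. In these, only 7 and 11 of the 23 signalling and Fuhc transcripts were detected, against all 23 in the other 3. The count depends on where detection begins: at a value of 200, the FcoR number in whole bodies was 33.8 and that in ampullae 29.2, while the FF numbers moved less.

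FF13 and FF15 were detected in all 26 combinations of sample class and colony, as were FcoR1, FcoR3, FcoR4, FcoR9, FcoR46, FcoR63 and FcoR72. These combinations leave out the negative fractions and the 2 sparse BSA libraries. A combination counted as holding a transcript that had a value of at least 1 in most of its libraries. At the other end, 7 FF transcripts, FF24, FF37 and FF42 among them, were held by 1 combination, and 4 by none. The median FF transcript was held by 6 combinations and the median FcoR transcript by 12. Of the whole-body genotypes, all 4 held the same 10 FF transcripts and the same 32 FcoR transcripts. Another 10 FF and 17 FcoR transcripts were held by 1 genotype only. By this rule, transcripts that only replicate 3 of the SMH libraries carried did not count for SMH. FF29 and FF9 stood there at 20654 and 4616 and counted for no whole-body genotype. FF4, FF7 and FF45, at 7166, 6548 and 2273 there, counted for 1 other genotype. The 23 signalling and Fuhc transcripts were held by all 26. Presence was not always the same in the replicates of a colony: 8.89% of whole-body combinations of FF transcript and genotype were detected in some replicates only, and 24.9% of those of FcoR transcripts in ampullae.

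The set of receptors followed the colony. The overlap of the detected FF and FcoR sets was measured by the Jaccard index, the number of shared transcripts divided by the number in either library. Whole-body libraries of a genotype overlapped by 0.90 ± 0.0772 on average (12 pairs) and those of different genotypes by 0.642 ± 0.0790 (54 pairs; one-sided permutation test, p = 7e-05). In ampullae the values were 0.760 ± 0.0829 within and 0.600 ± 0.115 between lines or colonies (one-sided permutation test, p = 4e-05). Male colonies kept much of their set over the budding cycle, with 0.864 ± 0.0420 within a genotype and 0.581 ± 0.0449 between genotypes. There p was 1e-05 (one-sided permutation test), the smallest that 100000 resamples can give. Still, 24.2% of the male combinations of FcoR transcript and genotype were detected at some stages only. Across tissues, ampullae and whole bodies of the same colony, SMGO or SMH, overlapped by 0.690 ± 0.0722 and those of different colonies by 0.622 ± 0.0373 (exact permutation test, one-sided, p = 0.005). This is the smallest p that its 400 permutations allow. The 3 blood individuals overlapped by 0.842 to 0.926, more than different genotypes in any of those classes did on average. Lines of SB825 ampullae overlapped by 0.768 within a line and by 0.757 between lines. This difference was not tested, and the first value includes SB825-FX replicate 1, which parted from the other replicates of its line.

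**Figure D1:**
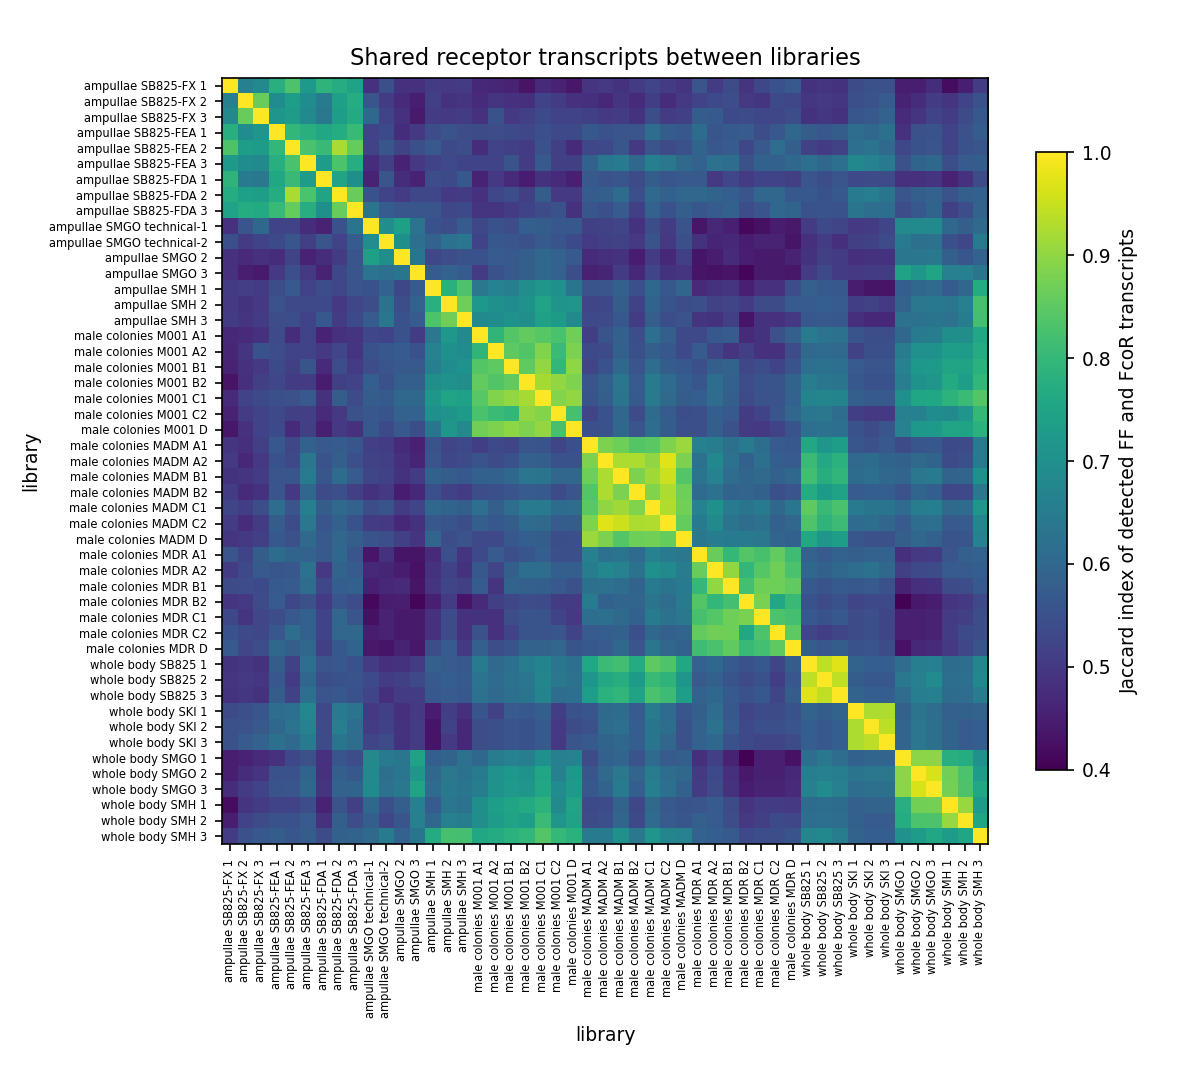
Jaccard index of the detected FF and FcoR transcripts between each pair of ampullae, male-colony and whole-body libraries, listed on both axes; colour gives the index on a scale from 0.4 to 1. Libraries of a male or whole-body genotype form bright blocks (mean 0.864 and 0.90), and whole-body SMH replicate 3 stands apart from replicates 1 and 2.

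Whole-body libraries asked which receptors differ between individuals in the same tissue. The largest differences lay in FF transcripts that were listed at 0 in some genotypes. Whether a genotype lacked such a gene or did not express it cannot be told from these values. FF10 stood at 78354 ± 1500.0 in SMGO (n = 3) and 52824 ± 17974 in SMH, and was listed at 0 in all libraries of SB825 and SKI. FF11 and FF33 were found in SKI alone, at 44672 ± 2383 and 36586 ± 2422, and FF24 and FF23 in SB825 alone, at 43081 ± 5291 and 29729.6 ± 7473. FF14 was present in SB825, SKI and SMGO and listed at 0 in SMH. Among the FcoR genes, FcoR18 stood at 20299 ± 674 in SMGO and 10757 ± 4141 in SMH, and at 0 to 5.83 in the other libraries.

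In limma, 86 of 110 tested whole-body transcripts passed an adjusted p of 0.05: all 25 FF, 47 of 62 FcoR and 14 of 23 signalling and Fuhc transcripts. Adjusted over the list alone, the counts were 25, 47 and 13. The adjusted p was 1.13e-12 for FF10, 7.34e-15 for FF11, 7.34e-15 for FF33, 1.34e-14 for FF24 and 2.65e-13 for FF23. FcoR48, which stood at 28340.4 ± 5159 in SKI and 9169 ± 696 in SB825, passed with 0.000825. FF4 (24919 ± 1668 in SKI, adjusted p = 0.00295) and FcoR12 (22650.4 ± 913 in SKI, 0.00100) were listed at 0 in SB825 and SMGO. In SMH these 3 were listed at 0 in replicates 1 and 2, and stood at 1981, 7166 and 1764 in replicate 3. FF3 was low in SKI, at 54.1 ± 53.3, and between 14141 and 20002 on average in the others. FF17 and FcoR72 were expressed in every genotype and still differed. FcoR72, the most abundant FcoR, averaged 165603 ± 17477 in SKI and 63784 ± 25476 in SB825 (adjusted p = 0.0164; 0.0728 without SKI replicate 1). The FcoR5 mean was 20383 ± 4789 in SB825 and 673 in SMGO. Signalling genes differed by smaller steps. PLC-g ranged from 4889 ± 979 in SMH to 13350.3 ± 555 in SB825, and SYK, a kinase that acts below activating immune receptors, from 5457 ± 729.7 to 13311 ± 1179.7 in the same genotypes. PLC-g and SYK were picked after their values were seen.

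Ampullae asked the same question in the tissue where colonies meet. FF10 and FcoR18 again marked SMGO and SMH, and FF5 and FcoR39 marked all 3 SB825 lines. FF10 stood at 58711 ± 7124 in SMGO (n = 3, the libraries named technical averaged) and 38934 ± 4319 in SMH, and at 0 in 8 of 9 SB825 libraries. FcoR18 stood at 17716 ± 4017 and 7383 ± 542 in SMGO and SMH and was listed at 0 in every SB825 library. FF5 averaged between 13690.1 and 14587 in the SB825 lines and FcoR39 between 11404 and 12312, while both were listed at 0 in SMH. FF9 and FF29 were SMH genes, at 8400.4 ± 1387 and 11491 ± 1308.

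Of 100 transcripts tested in ampullae, 61 passed in limma: 20 of 25 FF, 31 of 52 FcoR and 10 of 23 others. Adjusted over the list alone, the counts were 21, 31 and 9. With the SB825 lines alone, 1 transcript passed, and neither FF14 nor FF35 did. The adjusted p over all lines was 2.32e-06 for FF10, 4.30e-11 for FcoR18, 9.41e-07 for FF5, 9.80e-07 for FcoR39, 2.10e-10 for FF9 and 1.99e-07 for FF29. FF19 was listed at 0 in SMGO and averaged 7297 ± 1052 in SMH and 5009.5 ± 1608 in SB825-FEA. FF4 averaged 26735 ± 2744 in SB825-FDA and 16801 ± 1525 in SMH, against 166 in SMGO. FF17 and FF13 were present throughout and highest in SMGO, at 37968 ± 6998 and 16393 ± 1735. FcoR48, FcoR12 and FcoR38 were higher in SB825-FDA (16849.6, 7966 and 17351) than in SMGO (241, 176 and 542). FcoR70 stood at 8118 ± 1852 in SMGO and 2786 ± 1456 in SMH. In SB825-FX, replicate 1 parted from replicates 2 and 3: FF14 and FF35 stood at 11509.9 and 16512 in it and at 0 in the others, and FcoR38 at 13184 against 159.6 and 68.1. The abundant FF12 and FcoR72 did not pass (adjusted p = 0.324 and 0.257). FF12 passed without the averaged SMGO technical libraries (0.0123) and FcoR72 without SMH replicate 3 (0.0389).

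The comparison of ampullae with whole bodies asked which receptors the vessel tips carry, within the 2 colonies that gave both tissues. FuHc-Tm, the membrane-bound product of the Fuhc locus, was far lower in ampullae, and FuHc-Sec, the secreted one, was higher. FuHc-Tm averaged 272 ± 183 in ampullae and 17129 ± 2806 in whole bodies (n = 6 each). FuHc-Sec averaged 35188 ± 15786 and 14924 ± 3333. FF12 was higher in ampullae, 14437 ± 4460.3 against 4943 ± 3059.6, as were the kinases PI3K and the yes-like tyrosine kinase, which relay signals from immune receptors in other animals. FcoR72 was lower, 25297 ± 6748 against 80334 ± 22310.3.

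In limma with colony as a block, 35 of 81 transcripts passed, 20 higher and 15 lower in ampullae. Over all ampullae and whole-body colonies, without the block, 22 passed, and the balance turned to 6 higher and 16 lower, so the directions below hold for SMGO and SMH. Of the FF genes, 8 were higher and 1 lower (9 of 15); of the FcoR genes, 8 were higher and 7 lower (15 of 43); and of the others, 4 were higher and 7 lower (11 of 23). Adjusted over the list alone, the counts were 10, 14 and 11. On the log2 scale, FuHc-Tm differed by -6.27 ± 0.43 (SE, adjusted p = 1.03e-06), HSP40L by -1.34 ± 0.15 (3.48e-05) and FcoR72 by -1.66 ± 0.22 (0.000128). PI3K was higher by 1.39 ± 0.14 (1.80e-05), the yes-like kinase by 1.23 ± 0.16 (0.000128) and FF12 by 1.66 ± 0.34 (0.00235). FcoR41 rose from 846 ± 997 in whole bodies to 5947 ± 3451 in ampullae, FcoR38 from 13.8 ± 8.31 to 351 ± 229, FcoR70 from 1219 to 5452 and FcoR62 from 354 to 1876. The abundant FF17, FF2, FF3 and FcoR63 were higher by 0.63, 0.63, 0.47 and 1.20. Apart from FcoR72, the FcoR genes that were lower were not abundant in whole bodies. FcoR51, FcoR58, FcoR8 and FcoR20 averaged 386, 928, 507 and 623 there, FcoR24 2127, and each was at 0 in at least 4 of the 7 ampullae libraries. FcoR14 was listed at 0 in all SMGO and SMH ampullae, but it stood at only 10.9 to 62.0 in their whole bodies. The lowest values of at least 1 in these ampullae libraries were 28.1 to 86.8, so depth alone can give the 0. FF6 fell to 1144 ± 1112 from 3838 ± 1172 (adjusted p = 0.0332). FuHc-Sec (adjusted p = 0.00554) was picked after its values were seen.

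Some of these calls rest on few libraries. FF7, FcoR12 and FcoR48 passed as higher in ampullae (adjusted p = 0.00668, 0.0208 and 0.0455), but among the 6 whole-body libraries of SMGO and SMH they were listed at 0 outside SMH replicate 3, except FF7 at 13.9 in SMGO replicate 1. In SMH replicate 3 they stood at 6548, 1764 and 1981. Without whole-body SMH replicates 1 and 2, FcoR12 and FcoR48 did not pass (0.118 and 0.273), and in a fit over all ampullae and whole-body colonies FF7, FcoR62, FcoR70, FF17 and FF3 changed sign. FF10 (adjusted p = 0.0592; 0.0395 adjusted over the list alone), FF14, FcoR18, FcoR10 and FcoR1 did not pass. The FF total was 217212 ± 14670 in ampullae and 169343 ± 25406 in whole bodies, 1.29-fold higher (exact two-sided permutation test within colony, p = 0.005, the smallest of its 400 permutations). It was higher in both colonies, by 0.26 in SMGO and 0.48 in SMH on the log2 scale, but not over all colonies (log2 difference -0.09, exact two-sided permutation p = 0.690). The ampullae lines named SB825 had FF totals of 120061, 151254 and 156639, below the 174136 of whole-body SB825. This may not be a comparison within a genotype, and the labels do not say how these colonies are related. Their receptor sets overlapped by 0.538 on average, and FF5 and FcoR39, which marked the lines, were listed at 0 in whole-body SB825. The FcoR total went the other way, 106353 ± 6288 against 144528 ± 20891 (0.742-fold, exact permutation test, p = 0.01). FcoR72 alone set this direction: without it the FcoR total was higher in ampullae, 81056 ± 2166 against 64195 ± 6543 (1.27-fold, exact permutation p = 0.005, the smallest possible). The fall of the full total did not pass with whole-body SMH replicates 1 and 2 left out (log2 difference -0.23, exact permutation p = 0.05) or with a mean of log2 values in place of the sum (-0.34, exact permutation p = 0.13).

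**Figure D2:**
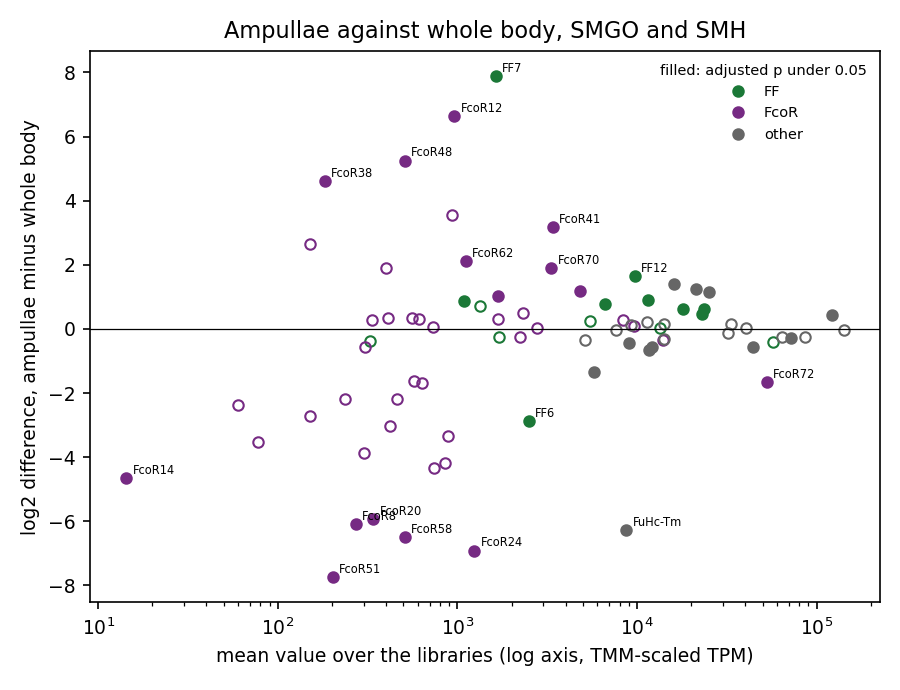
Each point is a transcript. The x axis gives its mean over the 12 SMGO and SMH replicates, the libraries named technical averaged as 1 (log axis, TMM-scaled TPM). The y axis gives its log2 difference, ampullae minus whole body. Filled points passed an adjusted p of 0.05 in limma. FuHc-Tm, at -6.27, is the only abundant transcript near the bottom, beside rare FcoR genes such as FcoR51.

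Male colonies asked for differences between 3 genotypes, each followed over the budding cycle. As in whole bodies, the largest differences were genes listed at 0 in a genotype. FF27 stood at 28512 ± 3599 in MDR (n = 7) and 10199 ± 1872 in MADM and was listed at 0 in M001. FF25 was found in MDR alone (23962 ± 3716), FF23 and FF14 in MADM alone (18042 ± 3361 and 11847 ± 1553), and FF10 and FF29 in M001 alone (12800.5 ± 1824 and 8558 ± 1582). Of the FcoR genes, FcoR17 and FcoR5 were MADM genes, at 25314 ± 1498 and 22898 ± 1975, and were listed at 0 in MDR.

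In limma with stage as a block, 85 of 106 transcripts passed between male genotypes: 27 of 28 FF, 44 of 55 FcoR and 14 of 23 others. The counts were the same adjusted over the list alone. The adjusted p was 3.59e-20 for FF27, 6.45e-20 for FF25, 6.45e-20 for FF23, 3.28e-20 for FF14, 3.47e-20 for FF10, 6.45e-20 for FF29, 1.32e-07 for FcoR17 and 6.74e-09 for FcoR5. FF4 and FcoR12 were listed at 0 in M001 and shared by MADM (13637 ± 1151 and 8746 ± 2097) and MDR (21759.7 ± 2281 and 8702 ± 1218). FF17 ranged from 502 ± 250.1 in M001 to 28050.0 ± 2092 in MADM and FcoR41 from 160.1 ± 206 to 24346 ± 3651 in the same genotypes. FF7, FcoR48 and FcoR72 were present in all 3 and differed less: FcoR48 averaged 6884 ± 2718 in M001 and 35872 ± 5519 in MDR, and FcoR72 26815 ± 2908 in MADM and 47589 ± 13439 in M001. FF12 differed least of the genes named here, from 9478 ± 915 in MDR to 11758 ± 1668 in M001 (adjusted p = 0.0198). It did not pass without stage A2 or stage B2 of M001 (adjusted p at most 0.0591).

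The same 21 libraries asked whether receptors follow the budding cycle, in which zooids are replaced by their buds at stage D, the takeover. FuHc-Tm was the transcript that did. It averaged 7939.7 ± 3053 at stage A1 (n = 3 genotypes), 7250.3 ± 1123 at A2, 11064 ± 1157 at B1, 11128 ± 2947 at B2, 19182 ± 5896 at C1, 25750.1 ± 10199 at C2 and 9159 ± 4459.7 at D. In each genotype it was higher at C2 than at any of A1, A2, B1, B2 and D.

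In limma with genotype as a block, FuHc-Tm alone passed over the 7 stages, with an adjusted p of 0.00708, among 108 transcripts tested. Adjusted over the list alone, 0 of 28 FF, 0 of 57 FcoR and 3 of 23 other transcripts passed, the 3 being FuHc-Tm, Shc and BHF. At an unadjusted p under 0.05 there were 8 transcripts, all signalling or Fuhc products. Without the genotype block FuHc-Tm did not pass (adjusted p 0.268). Shc, an adaptor protein, averaged 22552 ± 4409 at A2 and 29721 ± 3050.2 at C1 (adjusted p = 0.0560). It passed in limma's robust fit (0.0483), with stages merged to A, B, C and D (0.0187), or without any of 4 libraries: A2 of M001, C2 of MADM, and B1 or C2 of MDR. BHF was highest at D, 187743 ± 93229.9, and at A1, 155485 ± 74125 (adjusted p = 0.163), with B1 at 51553 ± 10034. SHP2 and ERK did not pass (0.331 and 0.371). No FF or FcoR gene, the abundant FF17, FF27, FF4, FF7, FF12, FcoR72, FcoR48, FcoR17, FcoR41 and FcoR5 included, passed in limma. The family totals did not differ between stages (permutation test within genotype, p = 0.290 for FF and 0.390 for FcoR). As a ratio to the sum of the other transcripts they did (permutation p = 0.0276 and 0.0364). That sum includes BHF and FuHc-Tm, whose means moved over the stages. The ratio can thus change through its denominator, and it does not show that the receptor families follow the cycle.

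**Figure D3:**
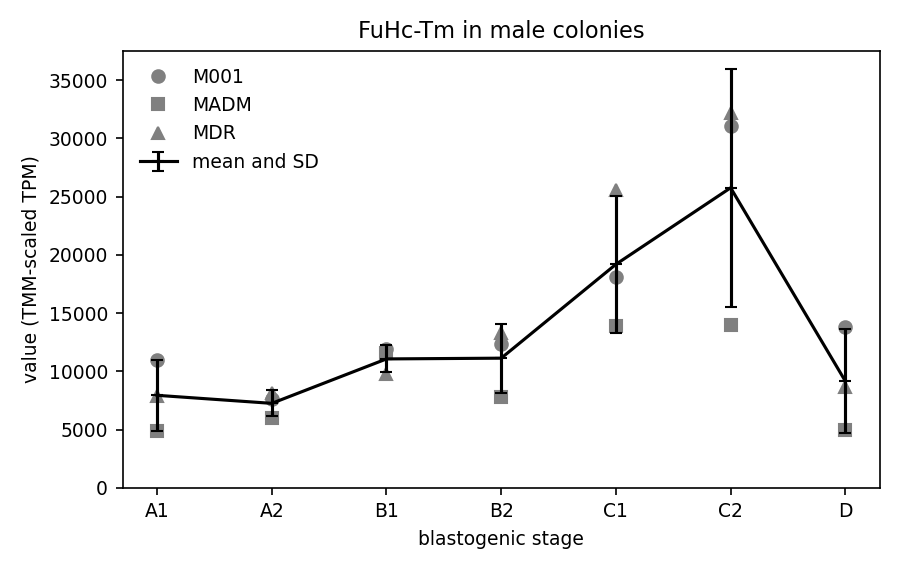
FuHc-Tm value (TMM-scaled TPM) on the y axis at each blastogenic stage on the x axis; symbols are the 3 male genotypes, and the line gives their mean with the SD. The mean goes from 7250.3 at A2 to 25750.1 at C2 and is 9159 at D.

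ALDH activity marks candidate stem and progenitor cells in many animals, and the sort compared positive with negative cells of 4 individuals. No receptor was found to differ between the fractions. The abundant FF12 and FcoR72 were found in both fractions of all 4 individuals. FF22 and FF29 were abundant in some individuals and low in others, in both fractions, though a difference between individuals was not tested. FF22 stood at 45813 and 41418 in the positive and negative cells of individual 2B, and at 62.6 and 0 in those of individual 6. FF29 stood at 28739.8 and 35825 in individual 6, and at 72.2 and 572 in 2B.

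In limma with individual as a block, 0 of 89 transcripts passed, and 0 adjusted over the list alone for FF (19 tested), FcoR (47) and others (23). At an unadjusted p under 0.05 there were 9: 1 FF, 2 FcoR and 6 others. The smallest p belonged to MEK, PAK1, FcoR63, Shc and NFAT. MEK averaged 40180.1 ± 4426 in negative and 24807 ± 886 in positive cells (n = 4 each), PAK1 13400.2 ± 3983 and 6249.9 ± 2548, and Shc 27053 ± 3934 and 17246 ± 2165. The adjusted p was 0.168 for these and for FcoR63, which averaged 946 ± 699 and 2794 ± 1744. NFAT averaged 2189 ± 846 and 4458 ± 1197 (adjusted p = 0.176). With values scaled to the receptor total, 3 transcripts passed, all lower in positive cells, Shc among them (0.0228). FF12, FF3, FF7, FcoR72, FcoR21, FcoR48, FcoR12 and FcoR1 did not pass. FcoR72 averaged 30425 ± 13848 in negative and 18502 ± 7085 in positive cells (adjusted p = 0.433). The FF total was higher in positive cells in 3 of 4 individuals (log2 difference 0.32, exact two-sided sign-flip permutation test, p = 0.25) and the FcoR total in 2 of 4 (0.18, p = 0.5), or, without FcoR72, in 4 of 4 (0.43, p = 0.13). The smallest p that 4 pairs allow is 0.13.

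Integrin alpha-6 has been used to sort candidate stem cells, germline precursors among them, in botryllid tunicates. The comparison covered individuals 81A and 81C, with 2 libraries per fraction each. FcoR54 was found in positive cells alone, at 385 and 354 in 81A and 283 and 425 in 81C, and was listed at 0 in the 4 negative libraries. In the individuals without a negative fraction, FcoR54 was listed at 0 in both libraries of 79C and 1 of 79G and stood at 185 in the other. FF22 and FF37 were abundant in 1 individual and low in the other, though a difference between individuals was not tested. FF22 stood at 49313 and 47159 in positive cells of 81C and at 0 in those of 81A. FF37 stood at 23056 and 25140.1 in positive cells of 81A and at 144 and 0 in those of 81C.

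In limma with individual as a block, FcoR54 was the 1 of 77 transcripts that passed (adjusted p = 0.000443) and the only 1 with an unadjusted p under 0.05. Adjusted over the list alone, 0 of 14 FF, 1 of 40 FcoR and 0 of 23 others passed. With a pseudocount of 500, which discounts low values, 0 passed (FcoR54 adjusted p 0.300). FF3, FF9, FF1, FcoR72, FcoR48, FcoR1, FcoR22_30, FcoR49, FcoR9 and FuHc-Tm did not pass. FcoR1 averaged 8528 ± 1209 in negative and 5994 ± 1823 in positive cells, and FuHc-Tm 1697 ± 633 and 3426 ± 1738. The FF totals were 111799 ± 20151 and 110207 ± 17089 and the FcoR totals 109846 ± 12569 and 109196 ± 16740 in negative and positive cells. No difference was found (exact two-sided permutation test within individual, p = 0.889 and 1). The smallest possible p was 0.0556, so the test could not pass 0.05. The log2 difference of the FcoR total, positive minus negative, was -0.23 in 81A and 0.19 in 81C.

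The labels call ALDH individuals 2B and 6 winners and 1 and 7 losers. With 2 individuals per outcome, no receptor passed the threshold. BHF, a Fuhc-locus product whose alleles predict fusion, averaged 125271 ± 36962 in winners and 59827 ± 11072 in losers (n = 2 each, both fractions averaged), with an adjusted p of 0.667 in limma. FcoR20 averaged 676 ± 318 and 5039.9 ± 920.2. FF14 stood at 10632 ± 269.8 in winners, and in losers it was found only in the negative cells of individual 7, at 3297. FcoR24 averaged 261 and 4899, and FcoR64 was listed at 0 in losers and averaged 314 ± 314 in winners.

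In limma, 0 of 100 transcripts passed between winners and losers, and 0 adjusted over the list alone for FF (20 tested), FcoR (57) and others (23). At an unadjusted p under 0.05 there were 3, 1 in each list. The abundant FF22, FF29, FF12, FF3, FF7, FcoR72, FcoR21, FcoR48, FcoR12 and FcoR1 did not pass. FF3 averaged 17773 ± 4443 in winners and 7477 ± 9618 in losers, and FcoR1 7359 ± 1604 and 3379 ± 2601. FcoR72 averaged 20809 ± 11554 and 28118 ± 7126.

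Across sample classes, with 1 value per colony or individual, FF41 was found in blood alone. It stood at 18794, 19339 and 15085 in the 3 blood individuals and was listed at 0 in every other colony compared. FF27 was found in male colonies (10199 in MADM and 28512 in MDR) and blood (1303 ± 632), and averaged 2.29 in whole bodies and 0 in the other classes. FcoR34 averaged 3734 ± 448 in blood and 17.0 ± 23.9 in ampullae. FF17 was abundant in ampullae, whole bodies and most BSA libraries and stood at 0 to 38.7 in blood. FF19 averaged 4276 ± 2652 in ampullae, 4086 ± 1679.7 in ALDH-positive cells, 2657 ± 2081 in male colonies and 1674 ± 2653 in whole bodies, and reached a value of 1 in no blood, IA6-positive or BSA library.

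In limma over 7 classes with 28 means per class and colony, 20 of 126 transcripts passed, 56 having an unadjusted p under 0.05: 8 of 37 FF, 11 of 66 FcoR and 1 of 23 others, which was Rac. The counts adjusted over the list alone were the same. The adjusted p was 8.49e-15 for FF41, 0.000195 for FF27, 0.000212 for FF19, 0.0373 for FcoR34 and 0.0363 for FF17. FF7, FF22, FcoR23, FcoR38 and FF2 also passed; FF22 was listed at 0 in ampullae and blood, and FcoR38 averaged 7633 ± 8276 in ampullae and 6.92 ± 9.56 in whole bodies. FF10, FF3, FF4, FF12, FcoR72, FcoR48, FcoR12, FcoR1 and FcoR18 did not pass; FF12 averaged 18005 ± 8837 in ALDH-positive and 1479 ± 670.4 in IA6-positive cells (adjusted p = 0.117). SMGO and SMH enter both as ampullae and as whole bodies, and the test treats these means as independent although receptor sets follow the colony. Without their ampullae 25 transcripts passed and without their whole bodies 16; FF41, FF27 and FF19 passed both times, FF17 and FF2 neither time. The receptor sets of the blood individuals overlapped by 0.842 to 0.926, and those of different SB825 ampullae lines by 0.757 on average. Their means may not be independent either, which bears on FF41 and FcoR38. Colonies other than SMGO and SMH gave 1 of the 7 classes each, so for them class and colony cannot be told apart. The count also moved with few samples. It was 60 without the BSA libraries SB07-09 and SB10-11, 8 with blood left out, 35 without SB04, 12 without FLLC2, and 13 without LFC4 or ALDH individual 2B.

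The FF total averaged 178954 ± 22104 in whole bodies, 171817 ± 42484 in ampullae, 170412 ± 32214 in ALDH-positive cells, 142072 ± 44474 in male colonies, 106447 ± 7877 in IA6-positive cells and 102182 ± 13862 in blood. The FcoR total averaged 182994 ± 65262 in whole bodies, 152305 ± 43368 in male colonies, 146572 ± 14142 in blood, 119820.0 ± 36379 in ALDH-positive cells, 111460.0 ± 6847 in ampullae and 105976 ± 5277 in IA6-positive cells. In the 5 BSA libraries the FF total was 130271, 117426, 136625, 0 and 42717. With all libraries the totals did not differ between classes (permutation test of F, p = 0.415 for FF and 0.564 for FcoR). Without SB07-09 and SB10-11 they did (permutation p = 0.00328 and 0.0241). Here too SMGO and SMH enter both as ampullae and as whole bodies, and the permutation treats these values as independent. No pair of classes passed after adjustment over 42 pairs (exact two-sided permutation tests, lowest adjusted p 0.12). At an unadjusted p under 0.05 there were 5 FF and 6 FcoR pairs. With 3 to 5 colonies per class a pair allowed only 20 to 252 splits. After adjustment almost no outcome could pass, so these tests do not decide whether pairs differ.

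**Figure D4:**
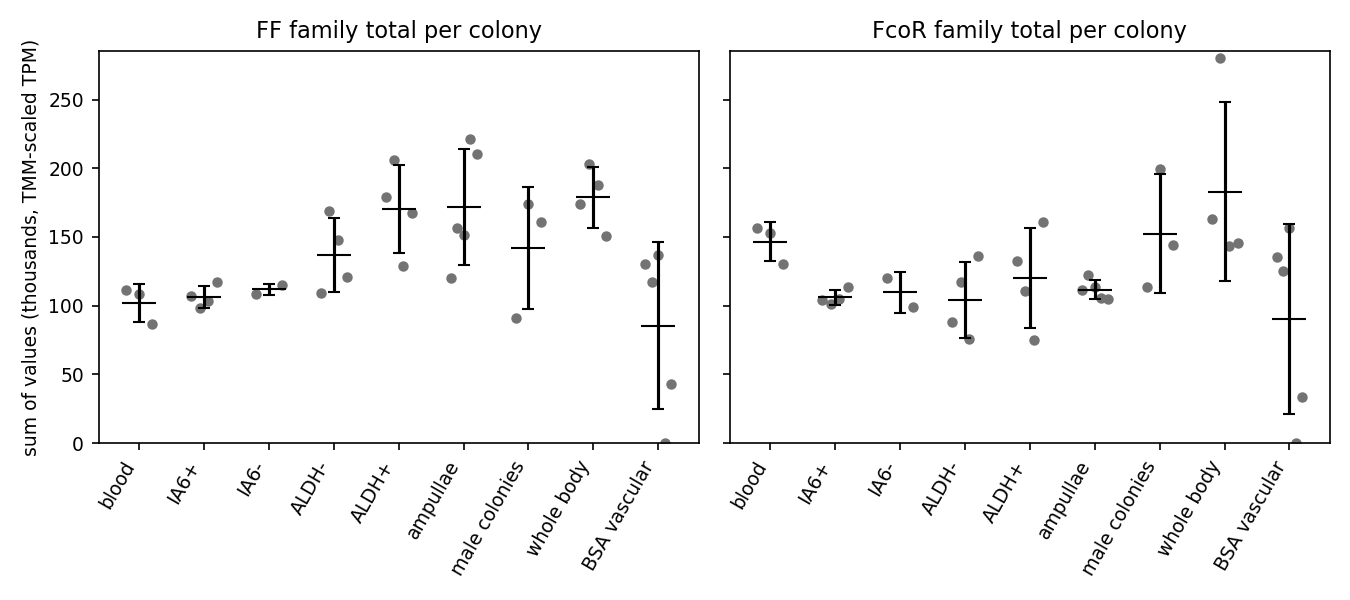
Sum of the FF values (left) and of the FcoR values (right) per colony or individual (in units of 1000, TMM-scaled TPM) for each sample class on the x axis; points are colonies or individuals, and lines are the mean and SD. Whole-body SKI has the highest FcoR total, 280007, and BSA library SB07-09 lies at 0 in both panels.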

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

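The tests of explanations and the counts over other splits in this part were chosen after the results were seen, as were the limits that define a marker transcript: at least 1000 on one side and a ratio of 10 or more to the other. A library is said to hold a marker when its value is no more than 10 times below the lowest on that side. Of 36 groups, 4 had a sample beyond the critical value at the 0.95 level of Dixon's test, where chance alone gives about 1.8. In male MDR the FF total at stage A2 was 135506, and at the other stages 159772 to 174405. In male M001 the FcoR total at stage B1 was 146953, and at the others 98138 to 113585. Whole-body SKI had an FcoR total of 280007 and the other genotypes 143226 to 162913; FcoR72 alone stood at 165603 in SKI. SMH ampullae held 20 FF transcripts and the other ampullae 16 to 17 on average. No biological explanation was tested for these 4.

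FcoR69 and FcoR40 changed between ampullae and whole bodies in different ways in SMGO and SMH, by a test of the difference itself in limma (2 of 81 transcripts passed, 12 at an unadjusted p under 0.05). FcoR69 was listed at 0 in all SMGO ampullae and stood at 563 to 1179 in SMGO whole bodies, while in SMH it stood at 962 to 2821 in ampullae and 349.8 to 1047 in whole bodies. The fitted contrasts on the log2 scale, which depend on the pseudocount where libraries are at 0, differed by 11.34 (adjusted p = 3.37e-05). FcoR40 stood at 206 to 1911 in SMGO ampullae and at 0 in SMH ampullae. In whole bodies it stood at 0 to 11.1 in SMGO and 0 to 8.91 in SMH. Its contrasts differed by -7.48 in the limma test (adjusted p = 0.0448). The SMH contrast of -1.10 rests on the whole-body value of 8.91. That value is below 28.1, the lowest value of at least 1 in SMH ampullae, so no change in SMH can be read from it.

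Of 9 transcripts that mark SMH ampullae against SMGO, whole-body SMH replicate 3 held 9 and replicates 1 and 2 held only 2, FF16 and FF44; FF4, FF9, FF19, FF29, FF45, FcoR22_30 and FcoR23 were absent or, for FF19 in replicate 2, at 258. Library depth is argued against, since the missing transcripts stood at a median of 4040 in replicate 3 and the lowest values in replicates 1 and 2 were 7.41 and 9.11. SMGO libraries under an SMH label are argued against too: FF14, the only marker of SMGO, was at 0 in both (0 of 1 held), and their overlap with SMGO whole bodies, 0.770 to 0.875, lay below that among SMGO libraries, 0.895 to 0.964, though above that with SMH replicate 3, 0.731 to 0.754. Another colony or a chimera that shares part of the SMH transcripts (2 of 9 held by both) cannot be told apart from a difference between pieces of SMH: the markers were chosen as those that all 3 SMH ampullae hold, and replicate 3 is the only other whole-body library of SMH. The labels name replicate 3 in another form than 1 and 2, so a different origin of the 2 sets may stand behind it.

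Ampullae SB825-FX replicate 1 resembled the lines FEA and FDA. It held 3 of 3 transcripts that mark these lines, FF14, FF35 and FcoR38, and 0 of 4 that mark FX replicates 2 and 3: FF11, FF40 and FF42 were at 0 and FcoR40 at 115, against 7482 and 9576. Library depth is argued against, since those 4 stood at a median of 3921 in replicates 2 and 3 and the lowest value in replicate 1 was 79.3. A mix of FX with FEA or FDA is argued against, since the 4 stood in replicate 1 at a median ratio of 0 to replicates 2 and 3, and at most 0.0135. A library of the FEA or FDA line under an FX label (3 of 3 held) remains a candidate explanation, beside siblings that inherit different receptors, which was not tested.

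The ALDH-negative library of individual 7 held transcripts that its positive library lacked. Of 11 transcripts that mark individual 2B against positive cells of 7, it held 10, at a median ratio of 0.33 to 2B (0 to 0.819), and all 3 that mark 2B alone, but 0 of 4 that mark individual 1 alone and 0 of 3 that mark 6 alone. Sorting by ALDH cannot be told apart from this: 12 transcripts of at least 500 stood 10 times or more above the positive cells in negative cells of individual 7 and at most 3 in the others, but 10, 1, 10 and 9 did so in positive cells of 1, 2B, 6 and 7, so fractions often differ by such numbers. RNA or cells of individual 2B, or of a colony with its receptors, may be present in this library, since 2B held 11 of those 12 and the 5 markers of positive cells of 7 stood at a median ratio of 0.533 in it (0.118 to 0.855), as a mix would give; sorting does not predict this but does not forbid it. Whether they came through handling or through fusion of colonies, which lets blood cells pass, was not tested, and the loser value of FF14 rests on this library.

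Splitting the samples at random into groups of the same sizes shows how often chance gives as many transcripts. For whole-body genotypes 1 of 100 splits, the real one, gave as many transcripts (86; highest of the others 27). The same held for ampullae genotypes (1 of 100, with 61 and 57) and ampullae against whole bodies (1 of 100, with 35 and 23). It also held for stages (1 of 100, with 1 and 0) and male genotypes (1 of 100, with 85 and 19). This share is the smallest that 100 splits can give, so chance is unlikely for these 5 but not excluded. For stages it rests on 1 transcript, and the tissue splits were drawn across colonies, not within them. For sample classes 2 of 100 splits gave as many, the real one with 20 and another with 23, a share under 0.05. For IA6 fractions 6 of 34 gave as many (1, and 1 at most in the others), so chance cannot be excluded. These splits were drawn across individuals, although the test has individual as a block. For ALDH fractions the real count is 0, which every split reaches (32 of the 32 that could be fitted; highest other 2), so the splits test nothing there.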

How the results depend on the processing

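Alternatives chosen after the data were seen are the pseudocount of 500, scaling to signalling genes, the ratio to other transcripts, the detection value of 200, SB825 ampullae only, SMGO or SMH only, blood left out, SMGO and SMH in 1 class only, FcoR totals without FcoR72, and leaving out individual 7, whole-body SMH, whole-body SMH replicates 1 and 2 together, or SB07-09 and SB10-11 together. Of 616 alternative values of the main results, 569 stayed the same. For counts of transcripts passing this means within 1.5 times the main count, and for means of detected transcripts within their SD. For tests it means the same side of the threshold and, where there is one, the same direction. Of 4265 values of named genes, 4051 kept direction and side of the threshold. Of the others, 153 no longer passed, 27 newly passed and 34 changed sign. Whole-body genotypes (80 to 89 transcripts) and male genotypes (78 to 96) stayed within 1.5 times the main count under every alternative, and the within-colony overlap of receptor sets passed under every alternative. Leaving out each library gave 57 to 63 for ampullae genotypes and 27 to 37 for ampullae against whole bodies. A replicate block gave 84, 61, 35 and 1 for whole-body, ampullae, tissue and IA6 comparisons, but residuals of libraries with the same number correlated by only -0.017, -0.0085, -0.051 and 0.071 on average, so the numbers mark no shared batch that shows, except perhaps in IA6, where 6 of 8 libraries lay closest to their own number (2 of 12, 6 of 15 and 1 of 12 elsewhere). Depth is unknown, so a value of 0 in a sparse library, the BSA ones above all, limits every statement on absence.

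For counts of transcripts, SB825 ampullae only gave 1 (fewer libraries and no other colony). In the tissue comparison, all colonies gave 22 (6 higher, 16 lower) and SMH only 20. For stages, scaling to the receptor total, robust limma and merged stages gave 2 each, no genotype block 0, and leaving out 1 library 1 to 2 (2 without A2 of M001, C2 of MADM, B1 or C2 of MDR; Shc was the second in each of these). ALDH with scaling to the receptor total gave 3, with a median of all differences of -0.197 against 0.059, and 0.268 with scaling to signalling genes; the latter moved the IA6 median from 0.169 to near 0. IA6 with a pseudocount of 500 gave 0, since FcoR54 lies below that value. Classes gave 60 without SB07-09 and SB10-11, 8 with blood left out, and 12 (without FLLC2) to 35 (without SB04) on leaving out 1 colony.

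For the family total between sample classes, FF, p was 0.0474 with the mean of log2, 0.00328 without SB07-09 and SB10-11 and 0.00536 as a ratio. For the family total between sample classes, FcoR, it was 0.0309, 0.0241 and 0.0207 in this order. Leaving out 1 colony gave 0.0146 (without SB07-09) to 0.525 for FF. Over stages the ratio gave a permutation p of 0.0276 and 0.0364, with BHF and FuHc-Tm, which moved over the stages, in its denominator. For FcoR in ampullae the log2 difference was -0.34 with a mean of log2 and -0.23 without whole-body SMH replicates 1 and 2. These replicates had FcoR totals of 172108 and 156463, against 108921 in replicate 3. The difference turned to 0.34 without FcoR72, the transcript that makes up the fall. The IA6 totals, near 0, changed sign: leaving out 1 library gave -0.18 to 0.15 for FF and -0.15 to 0.12 for FcoR, and a mean of log2 gave 0.47 for FcoR. At a detection value of 200, fewer transcripts counted by construction: FF 15 in blood and 13 in IA6-negative cells; FcoR 30.7 in blood, 31 in IA6-positive, 26.5 in IA6-negative and 37 in ALDH-positive cells, 29.2 in ampullae, 34.7 in male colonies and 33.8 in whole bodies.

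Named genes that changed sign, as log2 differences: with all colonies in the tissue comparison FF7 -0.45, FcoR62 -0.70, FcoR70 -2.21, FF17 -0.0183, FF3 -1.57 and FF14 -1.86, and with SMH only FcoR10 -0.27; on leaving out 1 library FcoR10 -0.088 to 0.24 and, for transcripts differing between ampullae and whole body: FF14 -0.00744 to 0.0495. In ALDH, FF3 0.015 with a pseudocount of 500, 0.17 with scaling to signalling genes and -0.24 to 0.15 on leaving out 1 library; FF7 -0.85 to 0.23, and 0.23 without individual 7; FcoR21 -0.84 to 0.039. Between winners and losers, leaving out 1 individual gave FF22 -10.98 to 1.44, FF29 -3.58 to 3.71, FF12 -0.36 to 0.64, FcoR21 -3.81 to 10.23, FcoR48 -8.66 to 5.70 and FcoR12 -7.69 to 6.30, and a pseudocount of 500 gave, for transcripts differing between winner and loser ALDH individuals: FcoR21 -0.0486. None of these passed a threshold under the alternative, and where no cause is named the cause was not tested.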

Other observations

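The test in this part was set before its result was seen; its repeat at a detection value of 200 was added afterwards. FuHc-Tm was low in the ampullae of every line and colony. It averaged 1022 ± 436 in SB825-FDA, 1574 ± 457 in SB825-FEA and 1699 ± 823 in SB825-FX (n = 3 each), 172 ± 140.2 in SMGO and 372 ± 186 in SMH. Whole-body means lay between 15525 in SMH and 23833 in SKI. FuHc-Sec went the other way, from 26360.3 ± 8891 to 53817 ± 12806 in ampullae and from 7992 ± 2180.1 to 15494 ± 1529 in whole bodies.

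The ampullae lines named SB825 shared fewer receptors with whole-body SB825 (mean overlap 0.538, 27 pairs of libraries) than whole-body SB825 shared with male MADM (0.777, 21 pairs). The first value crosses tissues and the second does not, so they are unlike measures, and the gap was not tested. Between ampullae and whole bodies of SMGO and SMH the overlap was 0.690 within a colony and 0.622 between the colonies. FF23, FF14 and FcoR5 were found both in whole-body SB825 and in MADM. In this order, FF23 averaged 29729.6 and 18042, FF14 16523 and 11847, and FcoR5 20383 and 22898. FF14 was also found in whole-body SKI and SMGO. Other transcripts parted the pair. FF24, at 37477 to 47992 in whole-body SB825, was held by only 1 combination of sample class and colony. FF4 and FF27 averaged 13637 and 10199 in MADM and were listed at 0 in whole-body SB825. The labels do not say how these colonies are related.

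Colonies that shared FF genes also shared FcoR genes. A genotype's set was taken as the transcripts detected in most of its libraries, so those that only SMH replicate 3 carried did not count for SMH. Over the 21 pairs of 7 whole-colony genotypes, whole-body and male, FF overlap ranged from 0.407 to 0.80 and FcoR overlap from 0.509 to 0.88, and they correlated with Pearson's r of 0.672 (one-sided exact permutation of genotypes, p = 0.000992, 5040 permutations) and Spearman's rho of 0.430 (p = 0.0214). Without SMH and SKI, the genotypes farthest from the median, r was 0.526 and rho 0.433 (exact permutation p = 0.025 for each). At a detection value of 200, r was 0.758 (p = 0.000198) and rho 0.570 (p = 0.00476). The result is consistent with FF and FcoR sets that are inherited together, but kinship between colonies or differences in library depth, which raise or lower both sets at once, could give the same correlation.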
